A study of Homo sapiens with 6 samples.

How the data were processed

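RNA of HepG2 cells was extracted with TRIzol and made into polyadenylated RNA libraries with the VAHTS Universal V6 kit, per the labels' protocols. The series' design text states 3 independent biological replicates in each of 2 groups, treated and control, and each library was placed in its group by its treatment label. The labels do not say from what cells the supernatant came, whether the replicates were grown or sequenced in batches, or whether replicate numbers pair libraries across groups.

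The values analysed were FPKM, fragments per kilobase of gene scaled to the total of each library, computed by the authors and deposited as a single table of 16112 genes by 6 libraries, with 7 further columns of annotation. The submitters' processing notes name fastp, HISAT2 and HTSeq, without versions or the settings used. The same notes name the mouse build GRCm38, while the gene symbols, gene identifiers and pathway codes of the table are human. The build and gene annotation behind the values are therefore not settled, and no coordinates are given. No listed gene is at 0 in all 6 libraries, and the table gives no gene biotype. How reads shared by near-identical genes were counted, and whether strand was used, is not given in the sources used here, so values of such copies and of genes overlapping on opposite strands are uncertain.

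FPKM carry no depth by themselves, but low values of a gene stood in whole-number ratios across libraries. A search for the gene lengths and library totals that make the values whole returned whole fragments for 100% of values in the 16112 genes, within 0.001 of a fragment, and the smallest such set of totals was taken, since whole multiples of it fit equally. On simulated tables the search returned 99.1% of counts exactly over 2349 genes and all 6 totals. The totals ranged from 31743242 to 35556551 fragments, of which 99.66% to 99.68% lay in the listed genes, and the 20 genes with the highest FPKM held 16.97% to 17.98% of the FPKM sum. These fragments served for depth and for an added voom fit, not for the main test.

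The main test was a linear model on log2(FPKM + 1) with group as the only term, fitted with limma 3.58.1 (lmFit and eBayes with trend, 2-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes with a mean of at least 1 FPKM over the 6 libraries entered, 9353 in all. Log2 differences are treated minus control on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. Over all 9353 genes their median was 0.08, and it was -0.0016 after median-of-ratios rescaling. A list median near 0.08 therefore marks no shift against the other genes. An exact permutation test of 3 libraries against 3 cannot go below p = 0.1, so none was run for single genes. A count of members adjusted over the list alone applies the same adjustment to the limma p of that list's measured members.

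There were 27 fixed gene lists, for hepatocyte functions, fetal liver, proliferation, stress responses, lipid metabolism, signaling, mitochondria, ribosomes and markers of other cell types. The 23 lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01 (2-sided, Benjamini-Hochberg over the lists), with camera at an estimated correlation, under which 0 lists passed, and with fry beside it, which called 2. With an estimated correlation, camera also takes its p from the few residual degrees of freedom that 6 libraries leave. At the preset correlation it does not, so a call lost between the 2 versions does not measure correlation alone. Fry tests whether the genes of a list move on balance in 1 direction and does not compare the list with other genes. The groups, the main test, the gene lists, the first group of alternatives below and the rule for named genes were chosen before the data were examined. That rule took up to 12 higher and 12 lower genes with the largest log2 difference among genes past the threshold with groups that did not overlap (none qualified), up to 4 measured members of each list with the smallest p, and always ALB, AFP, HNF4A, CYP3A4, CYP7A1, TTR, GPC3, MKI67, HSPA1A and MYC. Some genes that the rule takes are not reported here.

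The alternatives chosen beforehand were pseudocounts of 0.1 and 0.5, no minimum FPKM and a minimum of 5, median-of-ratios, TPM and quantile scaling, eBayes without trend or with robust fitting, the replicate number as a block, and leaving out each library in turn. Chosen after the data were seen were voom on the recovered fragments, voom with sample quality weights, array weights, and removal of each library's trend on GC content and gene length. The limma steps were tested on simulated data for the comparison of treated with control, with 9315 genes in the fit. Called were 42.4% of genes changed 1.5-fold, 89.4% of those changed 2-fold and 95.5% of those changed 4-fold, along with 11 unchanged genes. The simulated genes varied independently and with the same spread in both groups. In the real libraries the median SD of a gene was 0.18 (log2) in the treated and 0.13 in the control group. These shares therefore do not give the power in the real data. Figures were drawn with matplotlib 3.10.9.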

Results

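Gene expression was measured by sequencing of polyadenylated RNA in HepG2, a human liver cancer cell line that expresses many hepatocyte genes. The 6 libraries formed 2 groups of 3, sampled at 36 h. Cells of the treated group had received TSN from a high-temperature condition, which the series' title describes as tumor supernatant conditioned by mild hyperthermia and the design text marks with 42.5. The control group is marked with 37 in the design text, whereas the sample labels call these cells non-induced. Whether the controls received supernatant kept at the lower temperature or none is therefore not settled, and the differences below hold for the groups as labelled. The totals recovered from the FPKM were 34347131, 34679559 and 32420732 fragments in treated replicates 1, 2 and 3 and 31743242, 35556551 and 33022847 fragments in control replicates 1, 2 and 3. Between 14171 and 14362 of the 16112 listed genes had a value above 0 in each library.

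The comparison of the groups addressed whether the supernatant induces maturation of HepG2 cells, the question named in the series' title. As groups, genes for secreted hepatocyte proteins, the cell cycle, cholesterol synthesis and fatty acid synthesis stood higher in the treated libraries by camera with a preset correlation. None of these 4 calls held with an estimated correlation (adjusted p = 0.476, 0.317, 0.476 and 0.317 with an estimated correlation, in that order). Genes of the NRF2 antioxidant program, the heat shock response, the mesenchymal and TGF-beta response and the ribosome stood lower by the same test, and none of these calls held either (adjusted p = 0.511, 0.648, 0.317 and 0.788 with an estimated correlation, in that order). Treated replicate 1 lay far below the other libraries on the NRF2 and heat shock lists, at -0.63 and -0.44 (log2, centred on the 6 libraries), and the ribosome call was lost without that library (adjusted p = 0.115) or without control replicate 1 (adjusted p = 0.387). HP, which encodes the hemoglobin-binding plasma protein haptoglobin, had a mean of 41.9 ± 16.4 FPKM in the treated and 10.95 ± 0.923 FPKM in the control libraries (mean ± SD, n = 3 libraries per group, as for all values below). ALB and AFP, which encode the plasma proteins of the adult and the fetal liver, lay close together in both groups, at 7889 ± 696 against 7135 ± 413 FPKM for ALB and 494 ± 52.0 against 419 ± 31.9 FPKM for AFP. No single gene passed limma's test after Benjamini-Hochberg adjustment over 9353 genes, and the smallest adjusted p was 0.161.

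Among the secreted hepatocyte proteins, 22 of the 23 measured members had a higher mean in the treated group, with a median log2 difference of 0.31. The list passed camera (adjusted p = 4.59e-05), but the adjusted p was 0.476 with an estimated correlation. None of its members passed over all genes and 7 did when adjusted over the list alone, all of them higher; in 10 members each treated library lay above each control. The fibrinogen chain genes FGA and FGG averaged 457 ± 70.6 and 416 ± 114 FPKM in the treated libraries against 262 ± 24.6 and 211 ± 7.10 FPKM in the controls. For HPX, which encodes the heme-binding protein hemopexin, the means were 4.33 ± 2.29 and 0.973 ± 0.0848 FPKM. The thyroid hormone carrier gene TTR averaged 43.5 ± 4.90 against 35.1 ± 5.74 FPKM (limma adjusted p = 0.280).

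Other hepatocyte lists did not pass camera. The metabolism and urea cycle list had a median log2 difference of 0.25 over 17 measured members (camera adjusted p = 0.449), and its members with the smallest p went both ways. TAT, the tyrosine aminotransferase gene, averaged 3.28 ± 0.433 FPKM in the treated and 5.70 ± 0.346 FPKM in the control libraries, whereas the ketohexokinase gene KHK averaged 19.7 ± 5.43 against 11.6 ± 0.704 FPKM. These were the 2 members that passed when adjusted over the list alone. CPS1, which encodes the first enzyme of the urea cycle, averaged 3.55 ± 0.606 against 2.40 ± 0.346 FPKM. The drug metabolism list had a median difference of 0.04 over 17 members (camera adjusted p = 0.806) and no member passed over all genes or adjusted over the list alone. CYP3A4, the main drug-oxidizing cytochrome of adult liver, was near the floor at 0.0496 ± 0.0116 and 0.0183 ± 0.0136 FPKM and was not tested. ADH1A, an alcohol dehydrogenase gene, averaged 4.56 ± 1.37 against 2.30 ± 0.336 FPKM.

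In the list for bile acid synthesis and transport, the median and mean differences over 12 members were 0.06 and 0.03. The median over all tested genes was 0.08, and camera placed the list below the other genes (adjusted p = 0.806). AKR1D1, a reductase of bile acid synthesis, averaged 12.6 ± 1.19 against 7.69 ± 0.8001 FPKM, and the canalicular transporter gene ABCC2 averaged 277 ± 56.3 against 399 ± 36.4 FPKM; only these 2 members passed when adjusted over the list alone. CYP7A1, the rate-limiting enzyme of bile acid synthesis, averaged 2.83 ± 0.899 against 1.55 ± 0.623 FPKM with overlapping groups. Hepatocyte transcription factors had a median difference of 0.12 over 19 members (camera adjusted p = 0.806), and none passed over all genes or adjusted over the list alone. HNF4A averaged 55.6 ± 15.9 against 42.6 ± 1.37 FPKM and CEBPA 29.2 ± 12.6 against 15.0 ± 2.72 FPKM. Fetal liver and progenitor genes had a median difference of 0.23 over 19 members (camera adjusted p = 0.333). The imprinted gene PEG10, at 153 ± 25.9 against 95.3 ± 6.48 FPKM, was the 1 member that passed when adjusted over the list alone. GPC3, a glypican gene expressed in fetal liver and liver cancer, averaged 10.8 ± 1.26 against 9.61 ± 0.816 FPKM.

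The cell cycle list had the smallest camera p of the 23 tested lists (adjusted p = 2.30e-12), and its adjusted p was 0.317 with an estimated correlation. Its median log2 difference was 0.50 over 32 measured members, of which 31 had a higher mean in the treated group and 28 had each treated library above each control. No member passed over all genes, and 26 passed, all higher, when adjusted over the list alone. The thymidylate synthase gene TYMS averaged 43.0 ± 6.39 FPKM in the treated and 24.9 ± 1.17 FPKM in the control libraries. RRM2, a ribonucleotide reductase subunit gene, averaged 6.23 ± 1.01 against 3.22 ± 0.2999 FPKM, and the replicative helicase gene MCM2 15.6 ± 1.10 against 10.3 ± 0.243 FPKM. The mitotic kinase gene AURKB averaged 9.63 ± 2.01 against 4.74 ± 0.959 FPKM, and the proliferation marker MKI67 4.63 ± 0.875 against 2.54 ± 0.592 FPKM.

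Cholesterol synthesis genes had a median log2 difference of 0.47 over 23 measured members (camera adjusted p = 4.45e-07, and adjusted p = 0.476 with an estimated correlation). None passed over all genes and 14 did, all higher, when adjusted over the list alone. MSMO1, a sterol C4-demethylating oxidase gene, averaged 37.0 ± 4.32 against 18.1 ± 2.28 FPKM, and HSD17B7, a sterol ketoreductase gene, 12.6 ± 0.876 against 7.99 ± 0.687 FPKM. Fatty acid synthesis and lipid storage genes had a median difference of 0.41 over 15 members (camera adjusted p = 0.00184, and adjusted p = 0.317 with an estimated correlation). None of them passed over all genes, while 8 higher and 1 lower passed when adjusted over the list alone. The elongase gene ELOVL6 averaged 3.47 ± 0.268 against 1.83 ± 0.178 FPKM, and the stearoyl-CoA desaturase gene SCD 333 ± 25.0 against 244 ± 21.6 FPKM. Of the lists that passed camera, fry called the cell cycle list and this one (adjusted p = 0.0317 for each).

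**Figure D1:**
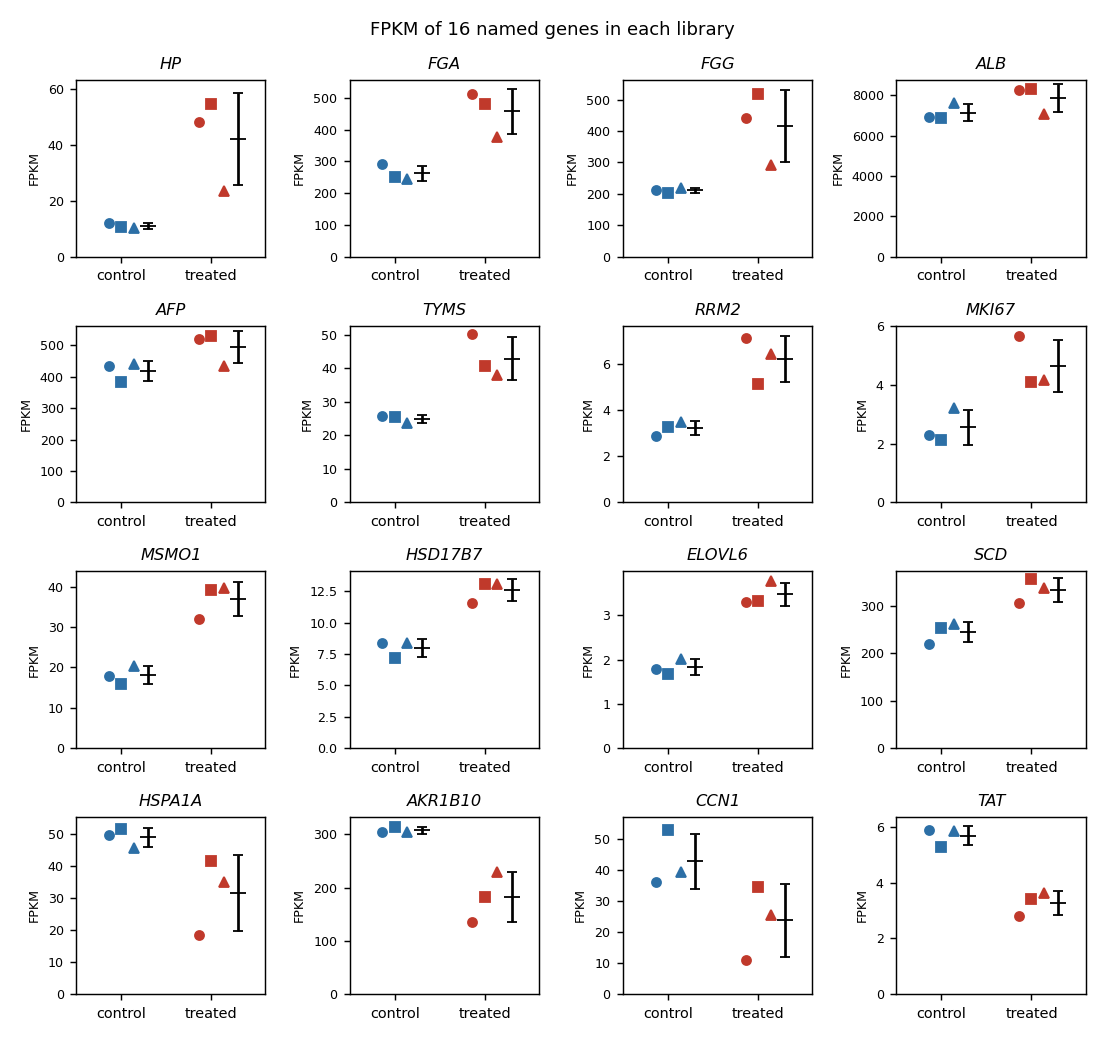
FPKM of 16 named genes (vertical axes, linear from 0) in the control libraries (blue) and the treated libraries (red), with circles, squares and triangles for replicates 1, 2 and 3 and black bars for the mean ± SD of 3 libraries. HP, FGA, FGG, TYMS, RRM2, MKI67, MSMO1, HSD17B7, ELOVL6 and SCD lay higher in each treated library than in each control, and HSPA1A, AKR1B10, CCN1 and TAT lower.

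Among the lower lists, the NRF2 antioxidant list had a median log2 difference of -0.31 over 20 measured members (camera adjusted p = 1.49e-07, and adjusted p = 0.511 with an estimated correlation). In 10 members each treated library lay below each control; none passed over all genes, and 3 lower and 1 higher passed when adjusted over the list alone. The aldo-keto reductase genes AKR1B10 and AKR1C1 averaged 182 ± 47.0 and 1378 ± 73.6 FPKM in the treated against 308 ± 6.25 and 1839 ± 76.8 FPKM in the control libraries. Treated replicate 1 stood apart on this list, with a mean over its members of -0.63 (log2, centred on the 6 libraries) against 0.03 and -0.02 in treated replicates 2 and 3 and 0.18 to 0.23 in the controls.

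Heat shock genes had a median log2 difference of -0.24 over 19 measured members (camera adjusted p = 8.13e-05, and adjusted p = 0.648 with an estimated correlation), and none passed over all genes or adjusted over the list alone. The inducible HSP70 gene HSPA1A averaged 31.6 ± 11.8 against 48.9 ± 3.03 FPKM, a value that is uncertain because reads can be shared with its near-identical copy HSPA1B. The co-chaperone gene BAG3 averaged 32.5 ± 7.29 against 43.1 ± 2.49 FPKM. Treated replicate 1 had the lowest mean of this list as well, at -0.44, against 0.09 and -0.06 in treated replicates 2 and 3 and 0.11 to 0.15 in the controls. In the mesenchymal and TGF-beta list the median difference was -0.31 over 14 members (camera adjusted p = 0.00803, and adjusted p = 0.317 with an estimated correlation), with no member past the threshold over all genes or adjusted over the list alone. This call was lost at a minimum of 5 FPKM (adjusted p = 0.0840) and after quantile normalization (adjusted p = 0.103). CCN1, a YAP target gene, averaged 23.7 ± 11.8 against 42.6 ± 8.91 FPKM and SMAD7, an inhibitor of TGF-beta signaling, 3.68 ± 0.484 against 5.18 ± 0.334 FPKM, whereas the smooth muscle actin gene ACTA2 averaged 19.2 ± 4.56 against 13.3 ± 2.43 FPKM. The mean of this list was -0.29 in treated replicate 1, -0.04 and -0.02 in treated replicates 2 and 3 and 0.07 to 0.19 in the controls.

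Ribosomal protein genes differed least among the called lists, with a median log2 difference of -0.08 over 26 members (camera adjusted p = 0.00116, and adjusted p = 0.788 with an estimated correlation). For none of them were the groups separate, and none passed over all genes or adjusted over the list alone; RPL11 averaged 985 ± 29.5 against 1067 ± 104 FPKM. The call was lost after quantile normalization (adjusted p = 0.690), without treated replicate 1 (adjusted p = 0.115) and without control replicate 1 (adjusted p = 0.387).

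**Figure D2:**
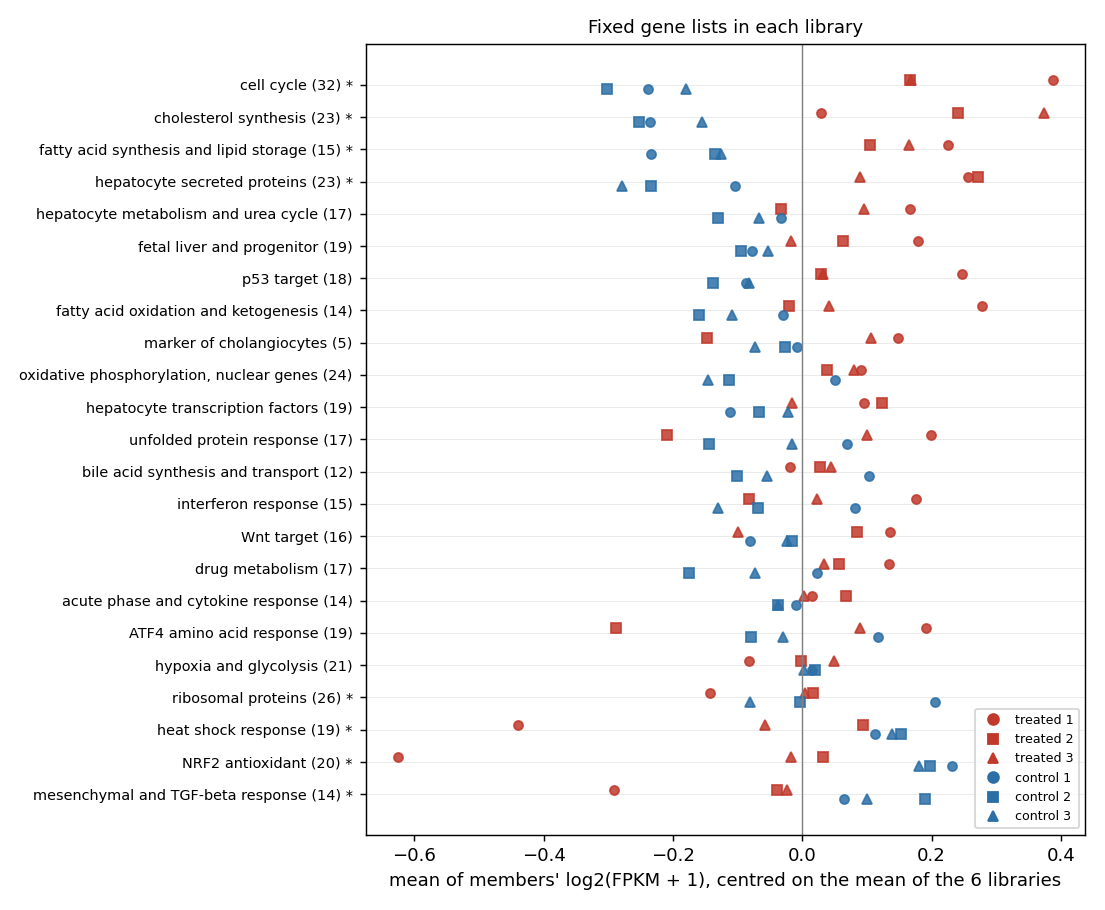
Mean log2(FPKM + 1) of the measured members of each of 23 gene lists in each library, centred on the mean of the 6 libraries (horizontal axis), with treated libraries in red and controls in blue, circles, squares and triangles for replicates 1, 2 and 3, the number of members in brackets and an asterisk on the 8 lists that passed camera with the preset correlation. On the cell cycle list the treated libraries sit between 0.17 and 0.39 and the controls between -0.30 and -0.18, while treated replicate 1 lies apart at -0.63 on the NRF2 list.

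Stress and metabolic lists that did not pass camera held members in both directions. The ATF4 list had a median difference of 0.01, a mean of -0.0050 and a camera adjusted p of 0.237 over 19 members; TRIB3 and SLC3A2, both ATF4 targets, passed as lower when adjusted over the list alone, at 321 ± 70.4 against 554 ± 45.2 FPKM and 600 ± 49.6 against 812 ± 93.9 FPKM. This list passed camera, as lower than the other genes, only without treated replicate 1 (adjusted p = 0.00849 with the preset correlation). In the main fit its camera adjusted p was 0.854 with an estimated correlation. The unfolded protein response had a median difference of 0.07 while camera placed it below the other genes (adjusted p = 0.806, 17 members), and no member passed adjusted over the list alone. For hypoxia and glycolysis the median was -0.0020 over 21 members and the camera adjusted p 0.465; the collagen prolyl hydroxylase gene P4HA1, at 23.9 ± 4.62 against 14.4 ± 1.20 FPKM, was the 1 member that passed adjusted over the list alone. Fatty acid oxidation and ketogenesis genes had a median difference of 0.18 over 14 members (camera adjusted p = 0.465), and 3 of them, ANGPTL4, ACADM and SLC25A20, passed as higher when adjusted over the list alone.

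The acute phase and cytokine list had a median difference of 0.02 over 14 members, camera placed it below the other genes (adjusted p = 0.864), and its members split. SERPINA3, an acute phase protease inhibitor gene, averaged 518 ± 97.9 against 289 ± 25.5 FPKM and the chemokine gene CCL20 451 ± 115 against 679 ± 25.3 FPKM; with ORM2 they were the 3 members that passed adjusted over the list alone. Interferon response genes had a median difference of 0.05 over 15 members (camera adjusted p = 0.864) and p53 target genes 0.23 over 18 (camera adjusted p = 0.154), with no member of either past the threshold adjusted over the list alone. Wnt target genes had a median of 0.05 over 16 members, with camera placing the list below the other genes (adjusted p = 0.806). TNFRSF19, a TNF receptor family gene, was the 1 Wnt target that passed adjusted over the list alone, at 9.99 ± 2.88 against 4.77 ± 0.250 FPKM, and MYC averaged 63.1 ± 8.40 against 58.5 ± 13.6 FPKM. Nuclear genes of oxidative phosphorylation had a median of 0.14 over 24 members (camera adjusted p = 0.115), and none passed adjusted over the list alone. They passed camera, as higher, without the minimum FPKM (adjusted p = 0.0145), at a minimum of 5 FPKM (0.0323) and after quantile normalization (0.00904). They also passed without treated replicate 1 (0.0440) and without control replicate 1 (0.00407). All of these calls used the preset correlation, and with an estimated one the camera adjusted p in the main fit was 0.788.

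Markers of endothelial cells and of fibroblasts and stellate cells were mostly near the floor. Those of immune cells and cholangiocytes were not all so, with the immune cell marker LYZ at 301 ± 132 against 312 ± 24.5 FPKM. None of the 8 listed endothelial markers and 1 of the 6 listed fibroblast and stellate cell markers, PDGFRB at 2.56 ± 1.61 against 2.38 ± 0.0907 FPKM, reached a mean of 1 FPKM over the 6 libraries. Of the 7 listed immune cell markers, 4 reached it, and CD14 passed as higher when adjusted over those alone, at 4.00 ± 1.20 against 2.16 ± 0.434 FPKM. The 5 measured cholangiocyte markers had a median difference of 0.18 (camera adjusted p = 0.806), and GGT1 passed as higher adjusted over the list alone, at 28.7 ± 0.790 against 20.4 ± 3.29 FPKM. None of the 13 genes of the mitochondrial genome was listed in the table.

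Over the 9353 genes tested with limma, 0 passed, 1788 had an unadjusted p under 0.05, and limma-voom on the recovered fragments likewise called 0, with 1764 at an unadjusted p under 0.05. Of the 1788 genes, 1237 were higher and 551 lower in the treated group, which is 69.2% higher. After median-of-ratios rescaling 51.0% of 1762 such genes were higher. With 1 library left out the limma count ran from 753 (without control replicate 2) to 3647 (without treated replicate 2). In 2264 genes (24.2%) the groups did not overlap, with 1483 above and 781 below the controls. The share by chance is 10% only as an average over all splits of the libraries into 3 and 3. Shares in other single splits were not computed, so an excess is not shown. The treated libraries differed more among themselves than the controls did: the median SD of a gene was 0.18 (log2) in the treated and 0.13 in the control group, and 67.9% of genes had the larger SD in the treated group. The first principal component took 68.1% of the variance and placed treated replicate 2, at 7.96, among the controls (6.12 to 18.5). Treated replicates 1 and 3 lay at -36.2 and -11.5. On the second component, with 16.1% of the variance, treated replicate 2 lay at -16.9, outside the controls (-2.29 to 13.2). Without treated replicate 2, limma called 2134 genes (1537 higher, 597 lower, 152 of them at least 2-fold). Among them were 23 higher cell cycle genes, 13 higher cholesterol synthesis genes and 11 lower NRF2 genes. For only 1478 of the 2134 genes (69.3%) did treated replicate 2 itself lie on the called side of the control mean. Without treated replicate 1, limma called 4 genes (3 higher, with MSMO1 and SLX1B among them, and RRAS2 lower). Without treated replicate 3 it called 3 (HP, SLX1B and FGG, all higher), while leaving out any 1 control called 0. SLX1B and RRAS2 lie outside the rule for named genes and were chosen after their values were seen, and SLX1B is uncertain because reads can be shared with its near-identical copy SLX1A.

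**Figure D3:**
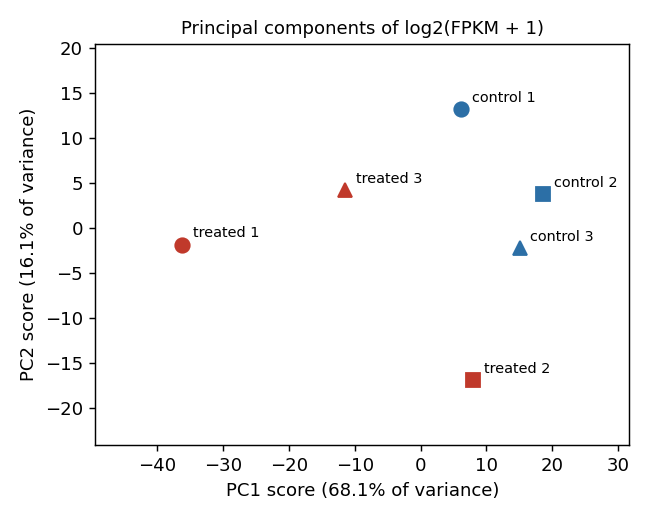
Scores of the 6 libraries on the first and second principal components of log2(FPKM + 1) over 9353 genes (axes in component units, with the percent of variance each takes), treated libraries in red and controls in blue. Treated replicate 1 lies at -36.2 on the first component and treated replicate 2 at 7.96, within the range of the controls. On the second component treated replicate 2 lies at -16.9, outside the range of the controls (-2.29 to 13.2).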

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

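The voom fits, the weights and the removal of GC content and length trends were chosen only after the result was seen; the other settings were planned. The 0 genes changed, raised, lowered or changed at least 2-fold stayed at 0 under 11 settings of pseudocount, filter, scaling, variance fit, voom and GC or length correction, and without any 1 control. With the replicate block 981 genes were called (680 raised, 301 lowered, 31 at least 2-fold). Deviations of same-numbered libraries correlated at 0.36, 0.35 and -0.36 across genes. Across the groups the libraries numbered 1 and those numbered 2 correlated best with each other, and those numbered 3 did not. This does not decide whether the numbers pair the libraries. The main fit had no block because no pairing is stated. Voom with quality weights called 3406 (2458 raised, 948 lowered, 209 at least 2-fold), and array weights called 50 (24 raised, 26 lowered, 26 at least 2-fold) in a fit that stopped before convergence. Treated replicates 1, 2 and 3 had quality weights of 0.38, 0.31 and 4.16 but array weights of 1.21, 1.03 and 0.011, and control replicate 2 had 2.78 and 12.2. Of the 981 genes called with the block, 944 were also called without treated replicate 2. Of the 2134 genes called without that library, 2052 were also called with quality weights. For the block and both kinds of weight the cause was not tested. Without 1 library each, the counts ran from 0 to 2134 changed, 0 to 1537 raised, 0 to 597 lowered and 0 to 152 at least 2-fold, the highest without treated replicate 2. Gene lists called were 7 to 9 against 8 in the refits that tested them, which leaves out both voom fits and the array weights. Camera with an estimated correlation called 0, and fry, which does not compare a list with other genes, called 2. Estimated correlations of the 8 called lists ran from -0.016 (mesenchymal) to 0.88 (ribosome), against the preset 0.01. Correlation alone does not account for the losses. The mesenchymal list, at -0.016, went from an unadjusted camera p of 0.00279 to 0.0336. The fatty acid synthesis list, with an estimated correlation of 0.026, went from 5.59e-04 to 0.0344. Camera with an estimated correlation also takes its p from the few residual degrees of freedom of the 6 libraries, unlike the preset version. None of the 103 named genes passed, so none could lose a call; over 20 settings a named gene gained one 214 times, under the block, the weights or without a treated library, and 8 values changed sign. The alternative restricted to protein-coding genes was not run because the table gives no biotype. Depth, 31743242 to 35556551 fragments, differed little between libraries and limits mainly genes near the floor such as CYP3A4.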

Other observations

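Pathway codes listed beside each gene in the deposited table were tested after the fixed lists had been seen, and the genes named in this part were chosen after their values were seen. Of 301 pathways with 10 to 300 tested members, camera with the preset correlation called 50, of which 26 were higher in the treated group, and none passed with an estimated correlation (smallest adjusted p = 0.479). Complement and coagulation cascades, the blood plasma defense and clotting proteins made mainly by hepatocytes, had a median log2 difference of 0.31 over 49 genes (camera adjusted p = 4.89e-05, and adjusted p = 0.479 with an estimated correlation), with 23 genes above and 3 below the controls in each treated library. DNA replication had a median of 0.35 over 29 genes (camera adjusted p = 8.06e-04, and adjusted p = 0.487 with an estimated correlation), and 15 of them were above and 0 below the controls in each treated library. The wider cell cycle pathway was not called, with a median of 0.12 over 104 genes (camera adjusted p = 0.158), of which 34 were above and 7 below. Neither was the ribosome pathway, with a median of -0.05 over 127 genes (camera adjusted p = 0.209). The fixed lists of both names passed camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.317 and 0.788). Glutathione metabolism was called higher, with a median of 0.26 over 37 genes (camera adjusted p = 0.0270, and adjusted p = 0.487 with an estimated correlation). The fixed NRF2 antioxidant list was instead called lower by camera with the preset correlation (adjusted p = 0.511 with an estimated correlation). Peroxisome genes had a median of 0.29 over 61 genes (camera adjusted p = 0.0106, and adjusted p = 0.599 with an estimated correlation). MAPK signaling genes had a median of -0.08 over 168 genes (camera adjusted p = 0.00237, and adjusted p = 0.479 with an estimated correlation), with 25 below and 17 above the controls in each treated library.

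Single genes with non-overlapping groups and a difference of at least 2-fold numbered 11 higher and 18 lower, none past the adjusted threshold. Without treated replicate 1 only 3 of the 11 and 1 of the 18 still differed at least 2-fold, and without control replicate 2 the numbers were 5 and 15. On the higher side stood METTL7A, at 21.5 ± 4.93 against 9.54 ± 1.06 FPKM (mean ± SD, n = 3), and TNFSF10, which encodes the death ligand TRAIL, at 4.50 ± 1.45 against 1.66 ± 0.252 FPKM. On the lower side stood RRAS2, a RAS family gene, at 25.2 ± 5.18 against 50.9 ± 0.267 FPKM, PFKP, the platelet-type phosphofructokinase gene, at 3.02 ± 1.58 against 7.96 ± 1.70 FPKM, and DUSP5, an ERK phosphatase gene, at 24.0 ± 12.4 against 54.9 ± 10.01 FPKM. Without treated replicate 1 the log2 differences of RRAS2, PFKP and DUSP5 were -0.83, -0.86 and -0.79, and those of METTL7A and TNFSF10 were 0.92 and 0.82. FABP1 and MTTP, which serve fatty acid binding and lipoprotein assembly in hepatocytes, were among the 30 genes with the smallest p, at 172 ± 15.1 against 99.2 ± 18.3 FPKM and 5.15 ± 0.499 against 2.86 ± 0.0991 FPKM. Immediate-early genes, a list written after the data were seen, had a median deviation of -0.68 (log2) from the mean of the 6 libraries in treated replicate 1, which held the lowest value for 19 of 21 measured members. The medians of the other libraries ran from -0.04 to 0.30.

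Of the tests that follow, those of library depth, of list means for a wrong label, of the gaps of the NRF2 and heat shock lists, of the first principal component and of splits at an unadjusted p were chosen only after the result was seen. The removal of GC content and length trends was also chosen after the data were seen. All tests of treated replicates 1 and 2 take up patterns that the fits had already shown. Leaving out treated replicate 2 moved the count of called genes from 0 to 2134. Its total was 1.05 times the median of the other libraries, which argues against depth, and removing GC content and length trends left 0 called genes with all 6 libraries, which argues against such a trend as the whole cause. The shares of genes leave open whether treated replicate 2 could be a wrongly labelled control. Where treated replicates 1 and 3 lay beyond 2 controls, treated replicate 2 did so for 69.9%, 61.3% and 67.1% of genes. The remaining control (1, 2 or 3 in turn) did so for 90.9%, 18.3% and 42.1%. The lowest-to-highest difference was -29.6 percentage points, but it sets shares of different genes against each other. Treated replicate 2 also lay above the 95% prediction interval of the controls on 3 of the 4 lists called higher without it. Its means on the secreted protein, cell cycle and cholesterol lists were 0.27, 0.17 and 0.24 (log2), against upper limits of 0.24, 0.06 and 0.04. Fatty acid synthesis, at 0.10 against 0.13, was the exception. The rule asked for all 4 lists, and the limits rest on 3 controls. On those 3 lists treated replicate 2 did not lie with the controls, but a wrong label of the library stays open. A weaker or later response of the culture of treated replicate 2 is an untested biological explanation. A response weaker on every list is not what its means show. On the secreted protein list its mean was 0.27, against 0.26 and 0.09 in treated replicates 1 and 3. On the cholesterol list the values were 0.24 against 0.03 and 0.37.

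The lower NRF2 and heat shock lists lean on treated replicate 1. Without it the NRF2 list kept 51.6% of its median difference and the heat shock list 52.98%. Camera with the preset correlation still called both without it (adjusted p = 1.78e-07 and 0.00318). With all 6 libraries neither camera call held with an estimated correlation (adjusted p = 0.511 and 0.648). For the NRF2 list the nearer of treated replicates 2 and 3 lay 0.15 (log2) below the lowest control, against a range of 0.05 among the controls, which argues against treated replicate 1 as the only source. For the heat shock list that gap was 0.0187 against a range of 0.04, so 1 library as the source stays open, and for that reason the shares kept do not decide the lists together. A difference from the treatment stays open for both lists, as a hypothesis.

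The higher secreted protein and cell cycle lists were set against the first principal component, on which treated replicates 1 and 3 lay apart from the controls. Treated replicate 2 lay among the controls on that component but exceeded the highest control by 0.38 (log2) on the secreted protein list and 0.35 on the cell cycle list, against ranges of 0.17 and 0.12 among the controls. Treated replicates 1 and 2 had means of 0.26 and 0.27 on the secreted protein list and 0.39 and 0.17 on the cell cycle list. The rule for deciding against the axis asked for more than 1 treated library among the controls on that component. Only treated replicate 2 lay there, so the test could not decide against it. The departure rests on 1 library, and the axis that parts treated replicates 1 and 2 stays open as a source of both lists. That secreted protein genes and cell cycle genes both rose with the treatment may hold as well, as a hypothesis found and tested on these same libraries. The preset camera calls behind it were lost with an estimated correlation (adjusted p = 0.476 and 0.317).

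The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In the count of called genes the real split gave 0 and the highest other split 0, so all 10 gave as many. At an unadjusted p under 0.05 the real split gave 1788 genes and the highest other split, treated replicates 1 and 3 with control replicate 1 against the rest, 2497, so 2 splits gave as many. For gene lists the real split called 8 and the highest other 12, again 2 splits with as many.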
